A study of Escherichia coli str. K-12 substr. MG1655 with 3 samples.

How the data were processed

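σ32 carrying a c-myc tag was immunoprecipitated from cells at 30 °C and from cells held at 42 °C for 5 min, and a mock precipitation with normal IgG was made at 30 °C, per the labels. DNA was crosslinked with 1% formaldehyde for 30 min and sheared to fragments of 200 to 400 bp, per the labels' protocols. CASAVA 1.4 is named in the submitters' processing notes. The aligner, the version of the genome sequence and the subtraction method are not given in the sources used here.

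The deposited values are a score, a signed signal per position and strand with minus-strand values negative, and positions with no remaining signal are not listed. Of the deposited scores, 93.4% at 30 °C and 92.3% at 42 °C were whole numbers within 0.011. Of the rest, 90.8% and 89.1% were whole numbers less a multiple of 1 fixed step, 1.357 and 1.32, which was read from the values as the weight of 1 mock read. The numbers of mock reads so recovered were equal at all 66872 positions that could be compared, so both profiles had the same mock library subtracted. Each whole unit was taken as 1 ChIP read, an inference from the values that no label states. The labels tie the mock sample to the 30 °C profile only. Summed signal was 3319220 at 30 °C and 2851330 at 42 °C, and no scaling between the profiles was applied. The design speaks of duplicates, and whether each profile pools them is not given in the sources used here.

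Absolute values of both strands were summed and averaged in 100 bp bins, of which there were 46396. Bins over the median plus 10 robust SD (1.4826 times the median absolute deviation) were joined when at most 200 bp apart. The robust SD was 0.203 at 30 °C and 0.199 at 42 °C. Regions overlapping between temperatures were counted as shared and compared with 1000 random placements. Each ratio is that of the highest bins of a region. Its exact binomial interval treats the bin's rounded signal as reads, which leaves out the error of the subtracted mock and any copies made by PCR. The interval of the median over regions is a binomial order-statistic interval. On simulated profiles, 38, 40 and 40 of 40 added regions were recovered at 30 °C for added heights of 2, 4 and 16 units per bp, and all 40 at each height at 42 °C, with 0 false regions. Each added region began at a bin edge, and the background was drawn from a simple model with its own threshold. These counts therefore check the procedure and do not measure recovery or false regions in the deposited profiles. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

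The bins, thresholds, ratios, most alternatives and the rule for named regions were chosen before the data were examined. That rule takes the 15 highest regions at 42 °C, up to 5 others highest at 30 °C, and the 5 highest and 5 lowest ratios among regions above the median height. Regions were to be given with their nearest genes, and 11 gene lists of known regulons and control operons were fixed for promoter signal. The gene table used with this work is of assembly ASM584v2, whose match to the profiles' sequence could not be established, so its coordinates were not used. Promoter signal of the gene lists, its ratio between temperatures and the σ32 promoter motif were therefore not analysed here, nor were the parts of the rule that needed genes. The comparison between temperatures stayed descriptive, with no p-value. Tests of technical explanations, among them Cochran's Q over regions, are given with the closing observations. Alternatives were another threshold, bin size, strand rule, overlap rule, scaling, pseudocount and region mean, and, chosen after seeing the data, a cap per position, a local median, no mock subtraction, subtraction of the median bin and division by the mock step.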

Results

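The binding of the heat shock sigma factor σ32 to the chromosome of Escherichia coli K-12 MG1655 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA crosslinked to a protein is pulled down with an antibody and sequenced. σ32 is the product of rpoH and directs RNA polymerase to heat shock promoters. The strain carried a c-myc tag on rpoH and was precipitated with an antibody against that tag. Cultures grown at 30 °C in minimal medium with glucose were brought to 42 °C with warm medium, or kept at 30 °C, for 5 min. The comparison open here is σ32 binding with and without this heat shock. The design names duplicates, but 1 profile per temperature was analysed, so there is no replicate error and no test between temperatures. The 30 °C profile listed 2245977 strand positions and the 42 °C profile 2013775, with 3804119 and 3367935 ChIP reads recovered from the values. All intervals are at 95%. Those on ratios of single regions and on read shares cover counting error only. The interval of the median ratio covers the spread between regions, which are not independent replicates, and not the variation between libraries.

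Regions are given by position on the sequence named NC_000913 in the profiles, which carries no version. No annotation of that sequence was used here, so the regions carry no gene names, and whether they lie in promoters was not examined.

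At 42 °C the σ32 signal stood above the background in 40 short regions, each 100 to 300 bp wide. The strongest, at 692601 to 692800, reached 45.3 units per bp in its highest 100 bp bin, which was 81.8 times the genome-wide median bin of 0.554. The regions at 494201 to 494400, 4368501 to 4368800, 3325601 to 3325900 and 1860501 to 1860800 followed, with 38.7, 36.7, 36.0 and 34.2 units per bp. Those at 661801 to 662100, 11901 to 12200 and 4366501 to 4366800 reached 21.1, 20.8 and 20.5. A further 7 regions exceeded 10 units per bp. They lay at 3865401 to 3865700 (15.4), 457901 to 458200 (15.3), 1338101 to 1338300 (13.8), 1027801 to 1028100 (12.8), 3643101 to 3643400 (12.4), 3527001 to 3527200 (12.2) and 1382001 to 1382200 (10.2). The other 25 regions held between 2.55 and 9.54 units per bp. Of all 40, 10 lay under 1.5 times the threshold of 2.54. The plus strand gave 38.5% to 58.0% of the signal of each region.

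**Figure D1:**
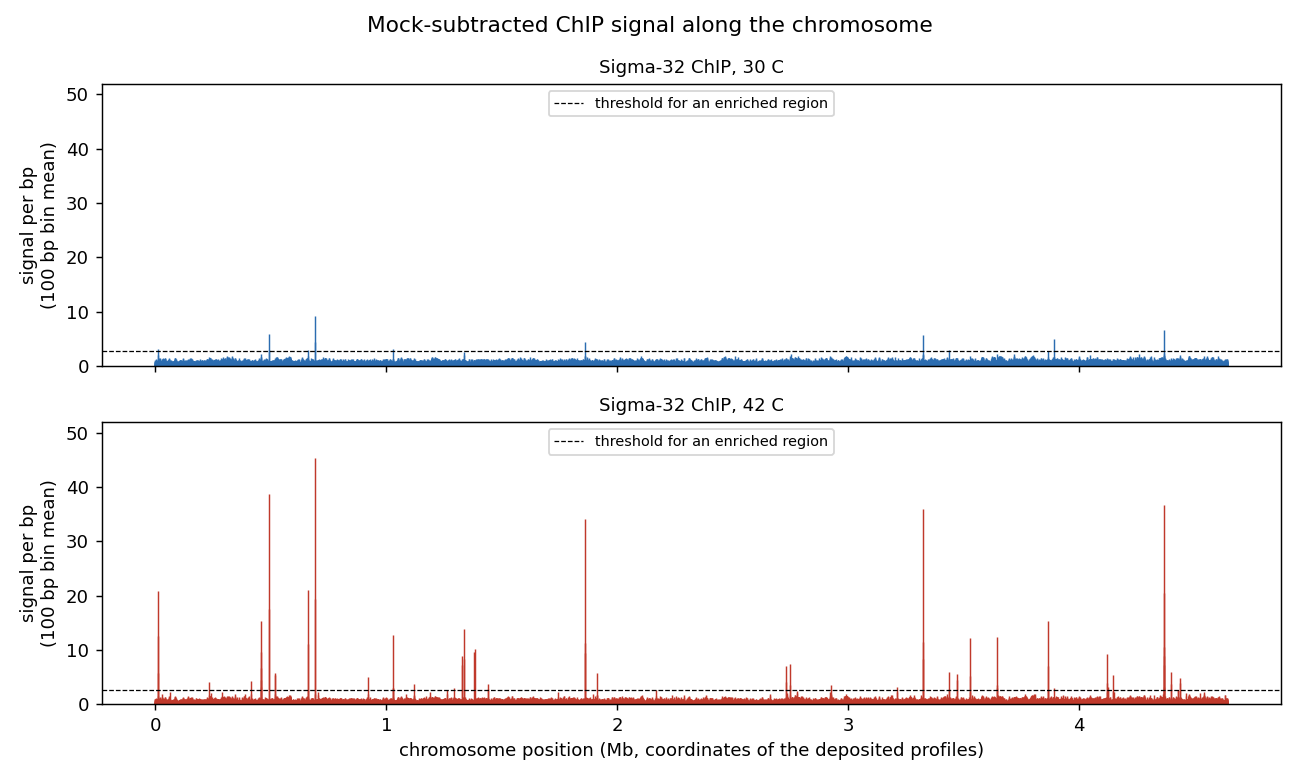
Mean signal per bp in 100 bp bins (vertical axis) along the chromosome in Mb (horizontal axis), at 30 °C above and 42 °C below, with the threshold for an enriched region as a dashed line. The highest bin at 42 °C, 45.3 units per bp, lies in the region at 692601 to 692800.

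At 30 °C the signal passed its threshold of 2.71 units per bp in 11 regions. The region at 692601 to 692800 was again the strongest, at 13.7 times the median bin of 0.673. Those at 4368501, 494201 and 3325601 held 6.56, 5.85 and 5.69 units per bp, and the region at 3889501 to 3889600 held 5.03. All 5 regions over 30 units per bp at 42 °C, and 9 of the 15 over 10, were among the 11, compared with 2 of the 25 weaker ones. 5 of the 11 lay under 1.5 times the threshold, and a threshold of 20 robust SD in place of 10 left 5 regions at 30 °C.

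All 11 regions at 30 °C overlapped a region at 42 °C. When the 42 °C regions were placed at random on the chromosome, the mean overlap was 0.018 and the highest of 1000 placements was 1. The same mock library had been subtracted from both profiles. Mock reads can be recovered at listed positions only, so background common to any precipitation could be measured only in part. In the highest 30 °C bins of the 11 regions the median was 53 mock reads, against 323 to 974 recovered ChIP reads. Background at the other positions could not be measured, and random placements do not address it. Of the regions at 30 °C, 4 of 5 were shared under the threshold of 20 robust SD and 7 of 8 when each strand had to pass alone. The other 29 regions passed the threshold at 42 °C alone. Of their highest 30 °C bins, 15 exceeded the 99th percentile of all 30 °C bins, against at most 3 in 1000 random placements. The same limit holds for these bins. Across the 40 regions, which are not independent replicates, Spearman's rho between the heights at the 2 temperatures was 0.745.

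Signal was higher at 42 °C in 39 of the 40 regions, and the counting interval of each of the 39 ratios lay above 1. For the 29 regions called at 42 °C alone the calling nearly fixed this direction. Of the 11 regions called at 30 °C, 10 were higher at 42 °C, with a median ratio of 5.59 over the 11, against 3.91 over the 29. With the median bin subtracted from each profile the median ratio over the 11 was 7.06. That was close to the 7.02 over all 40, a set that includes the 11. On the values as deposited, the median ratio of 42 °C to 30 °C over all 40 regions was 4.45 (95% interval of the median over regions 3.79 to 5.59), or 2.15 on the log2 scale. On the values as deposited, the region at 4366501 to 4366800 had the highest ratio, 9.61 (8.36 to 11.1), with 2.13 units per bp at 30 °C and 20.5 at 42 °C. Among regions above the median height of 6.50 units per bp it was followed by 1382001 (9.03, 7.46 to 11.1), 1860501 (7.80, 7.06 to 8.64), 661801 (7.14, 6.31 to 8.09) and 457901 (6.97, 6.05 to 8.08). With the median bin subtracted the order changed: the ratio was 13.7 at 4366501, 21.0 at 1382001 and 42.0 at 921101 to 921200, a weak region singled out after its values were seen, whose 30 °C bin of 0.779 lay close to the median bin. The lowest deposited ratios of this set were those of 1027801 (4.15, 3.66 to 4.71), 2748701 (4.18, 3.53 to 4.94), 2732101 (4.42, 3.71 to 5.28), 692601 (4.91, 4.57 to 5.27) and 1338101 (5.37, 4.70 to 6.16). The strong regions at 494201 and 4368501 had ratios of 6.60 (6.06 to 7.22) and 5.59 (5.15 to 6.09). Under a cap of 5 per position and strand, which their high bins saturate, the log2 ratio was 0.48 in place of 2.72 at 494201, 0.55 in place of 2.48 at 4368501 and 0.26 in place of 2.30 at 692601.

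The 40 regions cover 0.166% of the chromosome. They held 17342 recovered ChIP reads at 30 °C, or 0.456% (Clopper-Pearson interval 0.449% to 0.463%), and 75270 at 42 °C, or 2.23% (2.22% to 2.25%), a ratio of shares of 4.90. This set was largely chosen at 42 °C. All shares are of the reads recovered at listed positions, so ChIP reads at positions that the subtraction emptied are missing from them. The 11 regions as called at 30 °C held 0.173% (0.169% to 0.177%) and 0.939% (0.929% to 0.949%). The median bin was lower at 42 °C by a log2 difference of -0.28, opposite in direction to the regions. Subtracting the median bin from each profile gave a median ratio of 7.02, and capping each position and strand at 5 gave 2.70, a setting that by construction limits the highest bins most.

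**Figure D2:**
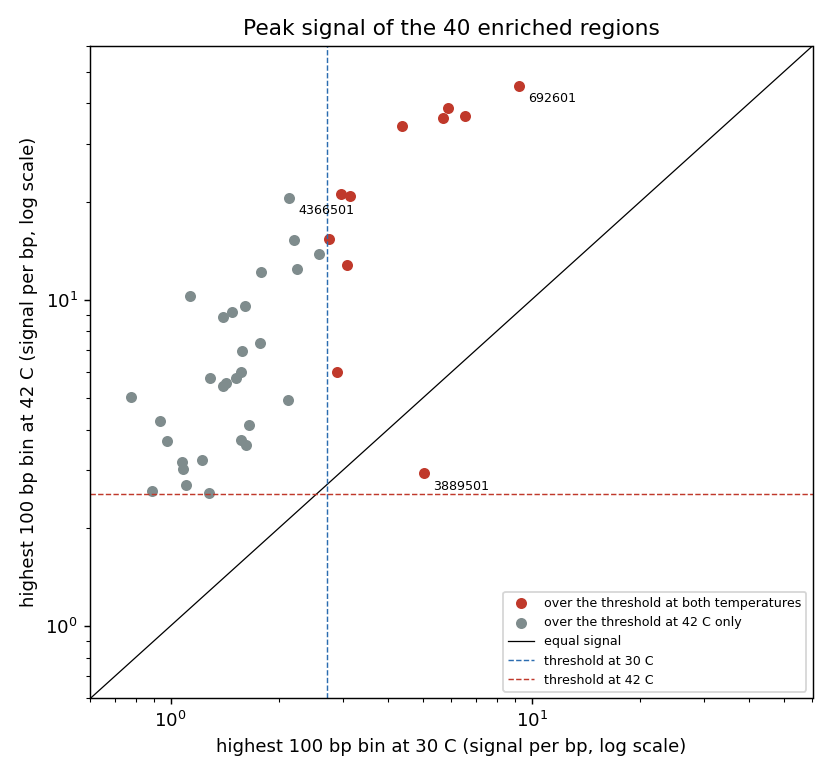
Highest 100 bp bin of each of the 40 regions at 30 °C (horizontal axis) and 42 °C (vertical axis), in signal per bp on log scales, with a line of equal signal and dashed lines at both thresholds; points are coloured by whether the region passed the threshold at 30 °C. 39 points lie above the line of equal signal and the region at 3889501 to 3889600 lies below it.

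The exception was the region at 3889501 to 3889600. It held 5.03 units per bp at 30 °C, the fifth highest of the 40, and 2.93 at 42 °C, where it ranked 37. Its ratio was 0.583 (0.503 to 0.674). The region at 3437501 to 3437700, which also passed both thresholds, held 2.90 and 6.02 units per bp, a ratio of 2.07 (1.80 to 2.40).

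**Figure D3:**
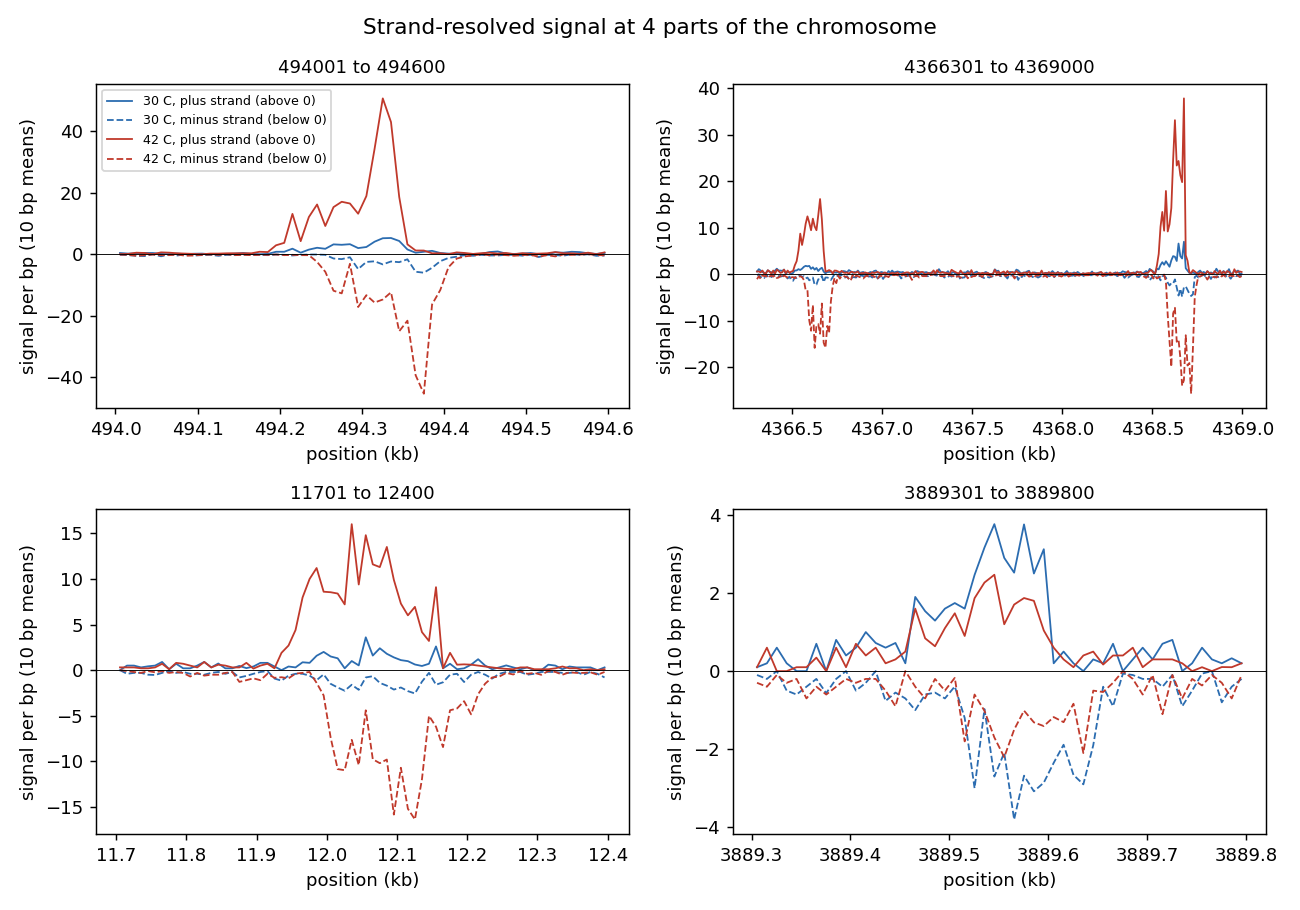
Signal per bp in 10 bp means (vertical axis; plus strand above 0, minus strand below) against position in kb (horizontal axis) around the regions at 494201, at 4366501 and 4368501, at 11901 and at 3889501, for 30 °C (blue) and 42 °C (red), each panel with its own scale. Of these 5 regions, the one at 3889501 was lower at 42 °C, with 2.93 units per bp against 5.03, and the other 4 were higher.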

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

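The cap of 5 per position and strand, the local 100 kb median, the reads without mock subtraction, the subtracted median bin and the division by the mock step were chosen after seeing the data. With a threshold of 20 robust SD, 5 regions were left at 30 °C, of which 4 were shared, and 28 at 42 °C. When each strand had to pass its own threshold, 7 of the 8 regions at 30 °C were shared, and with 50 bp bins 11 of 12. The median log2 ratio was 2.81 with the median bin subtracted, which by construction raises ratios that are above 1. It was 1.43 under the cap, which limits the highest bins by construction. The cause of the other changes was not tested. Under the settings other than 20 robust SD the numbers of regions stayed within 1.5 times those reported, at 8 to 12 at 30 °C and 35 to 41 at 42 °C. Under the other settings for the ratio the median log2 ratio lay between 1.99 and 2.37. In all 9 alternatives for the ratio, 39 of the 40 regions, and 10 of the 11 called at 30 °C, were higher at 42 °C. Scaling to the same sum, scaling to the same robust SD and division by the mock step each multiplied all ratios by a constant above 1. Under these settings the higher regions could only stay higher. Of 171 alternative ratios of the 19 regions chosen by rule, 66 moved beyond their counting interval, 105 did not, and none changed direction. 10 further alternatives chosen beforehand, for promoter signal of the gene lists, its ratio and the σ32 motif, were not run, because no annotation or sequence of the profiles' build was used here. No paired analysis was possible because there was 1 profile per temperature. The effect of depth on the calls was not tested.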

Other observations

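The tests of depth, of repeated reads and of a single yield factor were chosen after the result was seen, while those of the mock reads and of the minus-strand pile-up were stated first.

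The 3 closest pairs of neighbouring regions lay under 5 kb apart, and the smallest distance between starts was 2000 bp. The median bin of 100 kb windows was highest at 2700001 to 2800000 and lowest at 2200001 to 2300000 at both temperatures, with a ratio of 1.20 at 30 °C and 1.22 at 42 °C.

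The first pattern is the higher signal at 42 °C in 39 of 40 regions, and in 10 of the 11 called at 30 °C, whose direction the calling did not fix. A deeper library at 42 °C is argued against by the signal sums, whose log2 ratio of 42 °C to 30 °C was -0.22. Repeated reads beyond 5 at single positions are argued against as the whole cause. Under a cap of 5 the median log2 ratio over the 40 regions was 1.43, and 10 of the 11 called at 30 °C stayed higher at 42 °C. Up to 5 copies per position and strand pass this cap, so their part was not tested. One yield factor for all regions cannot be told apart from changes that differ by region. Cochran's Q was 32.3 (95% limit 16.9) over the 10 regions called at both temperatures that were higher at 42 °C. It was 15.7 (limit 15.5) without the region at 3437501, and 135 (limit 18.3) with the lower region at 3889501 added. The variances in Q count reads at 1 position as copies, which is wider than plain counting error. They leave out the variation between libraries, which is unknown. Differences between cultures stay open, as does non-specific precipitation that differs by temperature, because the only mock was made at 30 °C. Greater occupancy by σ32 after heat shock may account for the pattern but was not tested apart from these.

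The second pattern is the lower signal at 3889501 to 3889600 at 42 °C. Whether lower depth at 42 °C could be the whole cause was not settled. After scaling to the same sum the log2 ratio was -0.56 and the upper end of its counting interval was -0.35. Under counting error alone that argues against depth. With reads at 1 position counted as copies and the median bin subtracted, the unscaled ratio was 0.546 (0.343 to 0.869). This wider interval was not computed after scaling, and the region was picked for its lowest ratio. Signal also present in the mock cannot be wholly told apart from binding. In the region's highest 30 °C bin 51 mock reads were recovered. The other 39 regions had a median of 44 and a range of 1 to 105. Over all bins the median was 10 and the 99th percentile 47. At its listed positions the region's bin held 567 recovered ChIP reads at 30 °C, and 503 units were left after mock subtraction. The mock reads seen there were thus not the whole of its 30 °C signal. The median was 53 over the regions called at 30 °C, this one among them, and 40 over those called at 42 °C alone. Mock reads are visible at listed positions only, so bins with more ChIP signal show more of them. What the mock held at the other positions is unknown, which keeps its full share open. Variation between libraries, which could not be measured, or loss of binding at 42 °C may equally account for it.

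The third pattern is a minus-strand pile-up at 2753801 to 2753900 at 30 °C, which held 2.28 units per bp against 0.678 at 42 °C and stayed under the region threshold. The plus strand gave 14.7% of its signal, and position 2753881 alone held 61.3 units. With 1 read per position and strand the plus-strand share was 29.7%, below the middle 95% of bins (36.6% to 63.3%). This bin was picked for its strand asymmetry, while the bins of that range were not picked. The comparison therefore cannot decide whether copies of a few read positions are the whole cause. No biological explanation was tested.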
